A study of Mus musculus with 8 samples.

How the data were processed

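Single-cell RNA sequencing had been done on lung cells of C57BL/6J mice from 4 exposure groups with 2 libraries each. In every group 1 library held the pooled cells of 3 female mice (replicate 1) and 1 those of 3 male mice (replicate 2), per the labels, so that 24 mice entered 8 libraries. Lungs were digested with collagenase and DNase, red cells were lysed, live cells were sorted by the absence of DAPI staining, and libraries were made with the 10x Genomics droplet kit that tags the 3' ends of transcripts, per the labels' protocols. The sort, the digestion and the lysis can all set the share of a cell type, and epithelial cells were scarce in all 8 libraries. Control animals carry the word untreated in the series design and a vehicle abbreviation in the treatment label, and what animals without ozone breathed was not given in the sources used here.

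The deposited matrices hold counts, whole numbers of unique molecular identifiers (UMIs) per gene and cell barcode, per the file headers, which also name Cell Ranger 7.0.0. The genome build was mm10, per the submitters' processing notes, which name Seurat and edgeR as well. No deposited count had been normalised. The release of the gene annotation and the handling of intronic reads were not given in the sources used here. Coordinates below are on GRCm38, the assembly that mm10 names, from the GENCODE M21 annotation, in which 32235 of the 32285 gene identifiers of the files were found. Counting at 3' ends cannot tell copies of nearly identical genes apart, so genes of such families are less certain.

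The 8 libraries held 59751 barcodes with 432802080 UMIs. Barcodes with fewer than 200 detected genes (809) or more than 15% mitochondrial UMIs (728) were removed, which left 58214. Scrublet, run per library in scanpy 1.11.5 with an expected doublet rate of 0.8% per 1000 cells, marked 2210 of these (3.80%), and 56004 cells were used. Counts were scaled to 10000 per cell and log transformed. The 3000 most variable genes, without the response gene lists named below, mitochondrial genes, sex-linked transcripts and variable segments of antigen receptors, gave 40 principal components, a graph of 20 nearest neighbours and Leiden clusters at a resolution of 1.5 (leidenalg 0.10.2, igraph 0.11.9, Python 3.11.15). T cell clusters and clusters in which markers of 2 classes scored nearly alike were clustered again on 1500 variable genes and 20 components at a resolution of 0.8. The 93 clusters were named from marker lists, and a cluster needed at least 3 detected markers and no excess of another class's markers among its 10 leading genes. Class names therefore mean cells like that type by these markers. In all, 32 classes were named, and 1048 cells (1.87%) stayed unnamed. The unnamed share of the female and male library was 1.56 and 1.50% in control, 1.67 and 1.24% after ozone, 2.40 and 1.78% after allergen, and 2.87 and 2.05% after both. The marker lists, the gene lists, the designs, the rule for named genes and the alternatives listed below were fixed before the data were examined, whereas the scoring of clusters was set with the data at hand.

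For each class, counts were summed per library, since cells are not replicates. Libraries with at least 20 cells of a class entered, and a class was tested for a comparison where both libraries of each group did. edgeR 4.0.16 (R 4.3.3) with TMM scaling, its default filter on low counts and a robust quasi-likelihood fit tested each gene, with exposure group and sex of the pool as terms and all libraries sharing 1 estimate of the spread, which left 3 residual degrees of freedom in a class present in all 8 libraries. Every adjusted p for a gene is from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment within a class and a comparison, and genes under 0.05 were called. The comparisons were allergen against control, ozone against control, allergen plus ozone against control, allergen plus ozone against allergen, the interaction of both exposures (the ozone effect with allergen minus the ozone effect without it) and male against female. Counts of called genes are sums over classes. Levels are counts per 1000000 (CPM) of the summed UMIs, as mean ± SD over the 2 libraries of a group. Folds against a group without a UMI are lower bounds at a floor of 3 UMIs over the group. With 1 to 3 UMIs in the lower group the ratio is given with its exact 95% interval, which covers counting error only.

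Named genes follow a fixed rule. In each comparison of exposure groups, the 5 classes with the most called genes were taken. Within each, up to 3 genes with the largest rise and 2 with the largest fall are named among called genes that moved the same way in both sexes, were detected in at least 10% of the class's cells in a compared group, and reached at least 10% of the gene's level in the class where it was highest, a guard against free RNA. Predicted genes, antigen receptor segments, mitochondrial genes, Xist and Y-linked genes were left out. Members of the fixed lists could be named in their preset classes. A gene named by rank that is also a marker used to name its class (1 gene, Krt19 in alveolar macrophages) is left out of the text, which was decided after its values were seen. Genes of the sex comparison are Xist and the Y-linked genes, then the 5 others called in most classes.

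The 19 fixed lists were type 2 lymphocyte effector, alternative macrophage activation, type 2 chemokine, airway mucus and goblet, interferon response, NRF2 oxidant response, acute phase and metallothionein, inflammatory cytokine and chemokine, proliferation, immediate early and dissociation stress, surfactant and lipid synthesis, alveolar transitional state, MHC class II, extracellular matrix and fibrosis, lipid-handling macrophage, endothelial activation, hypoxia and glycolysis, immunoglobulin constant region, and free RNA of other cell types. The airway mucus, surfactant and alveolar transitional lists are for epithelial classes and were not tested, because no epithelial class reached 20 cells in both libraries of any group (65 type I, 30 type II and 52 ciliated cells in all). The others were tested in their preset classes with camera (limma 3.58.1) at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry, which asks whether a list's genes move one way on balance, each adjusted over all lists and classes of a comparison.

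Shares of a class among all cells of a library were tested with edgeR's quasi-likelihood test on cell numbers for the 29 classes with at least 50 cells. An exact two-sided permutation test over the 70 arrangements of 8 libraries compared the 4 libraries with each agent with the 4 without it. The smallest p it can give is 0.0286, and 2 libraries against 2 cannot reach 0.05 in such a test at all.

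The tests of genes, lists and shares were run on data simulated from the means and sizes of real libraries. In B cells 200 of 13447 genes were changed. For allergen against control edgeR called 68 of 100 changed 2-fold and 92 of 100 changed 4-fold, with 10 false calls. For the interaction it called 57 and 72, with 16 false calls. In regulatory T cells it called 21 and 73 for allergen and 3 and 53 for the interaction, with 2 and 3 false calls. The draws leave out the sample structure described below, which can add false calls. A 4-fold change in share for allergen was found in 29 of 50 simulations for neutrophils and 26 for type 2 dendritic cells.

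Alternatives were DESeq2 1.42.0 (its Wald test, or its size factors in the edgeR fit), no filter on low counts, a stricter filter on cells (at least 500 genes and at most 10% mitochondrial UMIs), called doublets kept, all variable genes for clustering, a resolution of 1.0, equal cell numbers per library, thinned UMIs, at least 50 cells per library, no sex term, only the 4 libraries of the compared groups, and each of the 8 libraries left out in turn. Chosen after seeing the data were a fit with the gene length trend of each library taken out (lowess span of 0.3), a fit without clusters of which over 90% came from 1 library, and a robust estimate of the dispersion. The robust estimate was used first and was set back to the default that the design implies after its counts had been seen, and the 2 gave identical counts of called genes.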

Results

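Cells were taken from the lungs of mice in a model of asthma made worse by ozone. Mice had received an allergen mixture of house dust mite, ragweed and Aspergillus (DRA), ozone (O3), both, or neither. The mixture was given into the nose in 5 doses of 20 µl on days 0, 5, 12, 14 and 17. Ozone was breathed at 2 ppm for 3 hours on day 18, and lungs were taken on day 19. Each group held 1 female and 1 male pool of 3 mice, so n = 2 throughout. In edgeR, p-values measure the spread of pools beyond a sex difference shared by groups. The libraries held between 5427 and 9129 cell barcodes. Median UMIs and detected genes per barcode ran from 5069 and 2075 in the ozone male library to 6847 and 2534 in the male with both exposures.

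B cells were the largest class, with 19826 of the 56004 cells used (35.4%). General capillary cells numbered 5321, and aerocytes, the thin capillary cells of the gas exchange surface, 2497. There were 4380 natural killer cells, 3960 CD4 T cells, 3148 CD8 T cells, 482 regulatory T cells and 2509 neutrophils. Nonclassical monocytes numbered 2268 and classical monocytes 2082. Interstitial macrophages (1238 cells), alveolar macrophages (1158), myofibroblasts (1137), adventitial fibroblasts (1076), alveolar fibroblasts (1020) and type 2 dendritic cells (591) followed. Epithelium was too scarce to analyse.

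**Figure D1:**
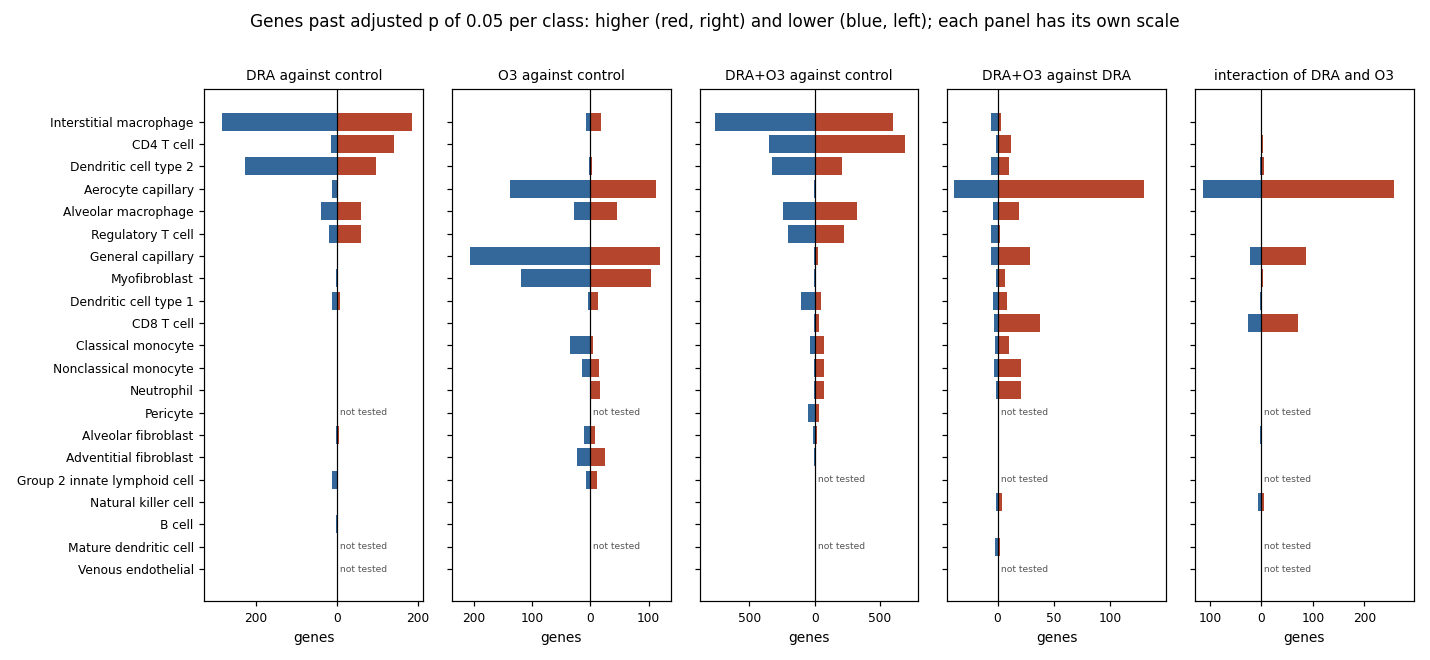
Number of genes called by edgeR's quasi-likelihood test at an adjusted p under 0.05 in each cell class, with 1 panel per comparison of exposure groups, each on its own scale. Red bars to the right count genes that were higher, blue bars to the left genes that were lower, with 470 genes in interstitial macrophages for allergen against control.

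Allergen against control shows the sensitised lung on day 19 without ozone. Interstitial macrophages rose from 0.714 ± 0.157% to 2.27 ± 0.241% of cells (mean ± SD, n = 2), type 2 dendritic cells from 0.669 ± 0.128% to 1.53 ± 0.216%, and CD8 T cells from 3.32 ± 0.565% to 7.67 ± 1.71%. Myofibroblasts fell from 3.10 ± 0.681% to 0.751 ± 0.192% of cells, alveolar fibroblasts from 3.05 ± 0.152% to 0.881 ± 0.175% and adventitial fibroblasts from 2.92 ± 0.538% to 1.02 ± 0.0812%. Pericytes and venous endothelial cells fell by 1.55 and 2.03 on the log2 scale. In edgeR's quasi-likelihood test of these shares the log2 changes of the first 3 classes were 1.68 (SE 0.47, adjusted p = 0.0449), 1.19 (SE 0.31, adjusted p = 0.0361) and 1.2 (SE 0.30, adjusted p = 0.0361). That of myofibroblasts was -2.02 (SE 0.38, adjusted p = 0.0260). The exact two-sided permutation test of the 4 libraries with allergen against the 4 without gave p = 0.0286, the smallest it can give (adjusted p = 0.118), for 7 classes, among them regulatory T cells (1.44 against 0.403%), alveolar macrophages (1.44 against 2.61%) and smooth muscle (0.0697 against 0.191%). Shares sum to a fixed total and depend on digestion and the live-cell sort. The 8 classes called by edgeR became 0 (7 at an unadjusted p under 0.05) without the DRA female library, 4 without the DRA male, 1 without the female control, and 0 (6 unadjusted) when shares were taken within immune and other cells separately.

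**Figure D2:**
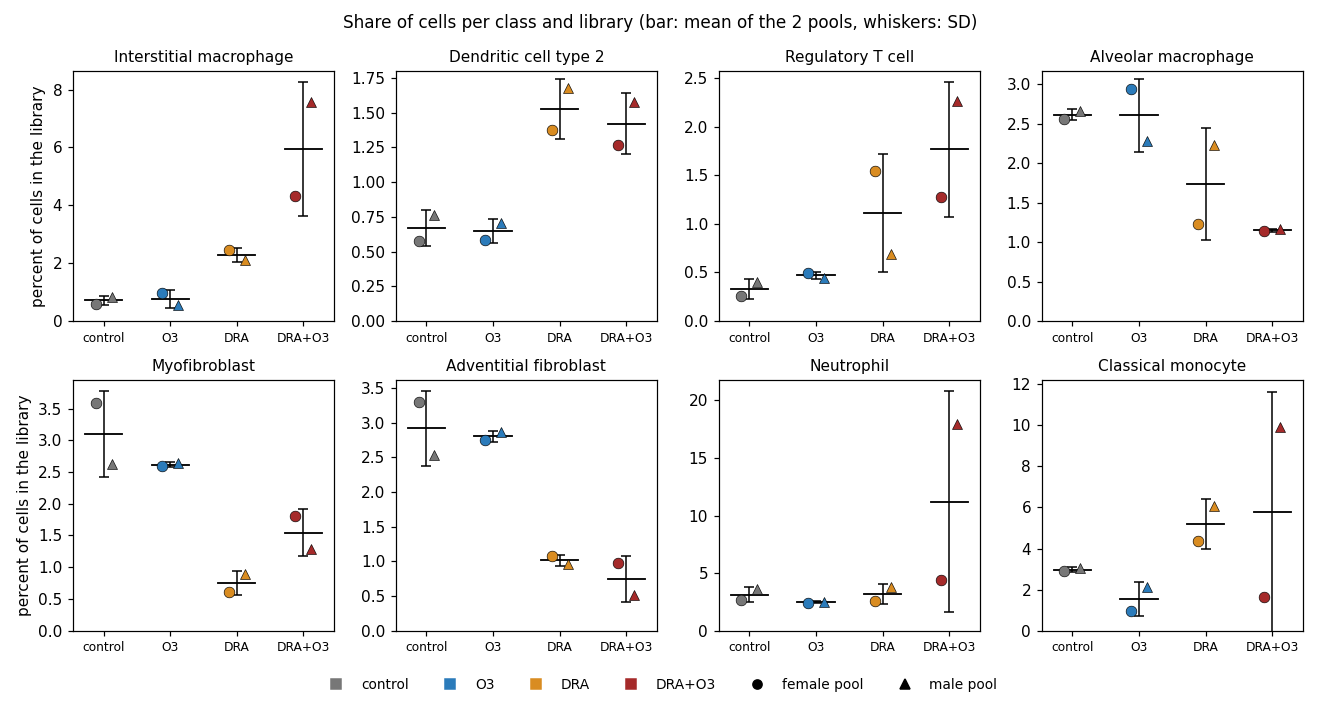
Percent of the cells of each library in 8 cell classes, with exposure groups along the horizontal axis, circles for female and triangles for male libraries, bars at the mean of 2 libraries and whiskers for the SD. Interstitial macrophages lay at 0.714% in control and 2.27% after allergen.

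CD4 T cells of allergen-exposed lungs held more transcripts of the type 2 lymphocyte effector list. Of its 16 measured members 6 rose and 0 fell, and 13 rose when adjusted over the list alone. Tnfrsf4, the costimulatory receptor OX40, rose by a log2 change of 1.93 (SE 0.20, adjusted p = 7.89e-04), Tnfsf11, the ligand RANKL, by 1.56 (SE 0.24, adjusted p = 0.00643) and Il10, an anti-inflammatory cytokine, by 2.38 (SE 0.41, adjusted p = 0.0155). Ccr8, a chemokine receptor of type 2 and regulatory T cells, and the transcription factor Batf rose by 2.16 and 0.81. Il13, the cytokine behind mucus production in allergic airways, was at 0 UMIs in control and at 2.62 ± 2.35 CPM (counts per 1000000 UMIs of the class) after allergen, at least 5.85-fold higher (adjusted p = 0.0327). Unnamed cluster 10.2, with Il13 and Il4 among its leading genes, lies outside the class, so these levels leave out its 198 cells. The list passed camera (adjusted p = 1.03e-18, and 0.218 with an estimated correlation). In regulatory T cells 2 of 10 members rose and 3 when adjusted over the list alone, Tnfrsf4 by 1.89 and the transcription factor Bhlhe40 by 1.64. Camera gave adjusted p = 4.26e-07, and 0.241 with an estimated correlation. Among genes named by rank in CD4 T cells, Hlf, a bZIP transcription factor that also marks group 2 innate lymphoid cells, rose by 3.08 (SE 0.27, adjusted p = 3.85e-04). The carboxypeptidase Cpd rose by 2.86 (SE 0.33, adjusted p = 0.00187) and the clathrin adaptor Hip1 by 2.70 (SE 0.45, adjusted p = 0.0309), while Tex14 and Pou6f1 fell by 1.04 and 0.88 on the log2 scale. Bhlhe40 in regulatory T cells was no longer called with each library's trend with gene length taken out, at nearly the same change (1.62, SE 0.42, adjusted p = 0.0606). In regulatory T cells Hip1 was higher by 20.2-fold (exact 95% interval 5.49 to 168, adjusted p = 0.00493) and the metalloprotease Adam12 by 19.9-fold (exact 95% interval 3.46 to 797, adjusted p = 0.00879). The proliferation list had 2 of 27 members up in CD4 T cells, Cdk1 and Top2a at 1.39 and 1.10, and 11 when adjusted over the list alone. Camera gave adjusted p = 1.31e-11, and 0.317 with an estimated correlation. Different clusters led the CD4 class, 5.1 in control (28.8%) and 10.0 (19.3%), with Cd40lg, Tnfsf8 and Tnfsf11 in front, after allergen, and regulatory T cells were led by 10.6 (55.3%) and 10.3 (42.2%). The 155 genes called in CD4 T cells (141 up, 14 down) became 0 by edgeR without the female control library (904 at an unadjusted p under 0.05), and 41 without the male control. They were 97 and 579 without the DRA female and male, and 264 and 274 without the female and male library of both exposures, which share the estimate of spread.

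Interstitial macrophages changed in 470 genes after allergen. Chil3, the chitinase-like protein Ym1, went from 2.60 ± 0.60 to 3547 ± 2097 CPM, a ratio of 1423-fold (exact 95% interval 487 to 6902, adjusted p = 4.00e-05). Timp1, an inhibitor of metalloproteinases, and the myeloid receptor Tarm1 were at 0 UMIs in control and at least 11.4-fold and 11.4-fold higher (adjusted p = 0.00946 and 0.00328). Cfap299 and Tcim fell by 5.38 and 4.17 on the log2 scale. Of the 15 measured genes of the alternative macrophage activation list 4 rose (8 over the list alone) and 0 fell. Arg1, arginase 1, was 92.3-fold (exact 95% interval 31.5 to 448, adjusted p = 3.23e-05) higher, and Pdcd1lg2, the checkpoint ligand PD-L2, 47.9-fold (exact 95% interval 13.2 to 397, adjusted p = 0.00505) higher. The ribonuclease Ear2 rose by 1.35 (SE 0.23, adjusted p = 0.0102). That list passed camera (adjusted p = 1.03e-18, and 0.218 with an estimated correlation). Enzymes of the hypoxia and glycolysis list rose, 5 of 14 with 0 lower and 8 over the list alone, among them Pgk1 by 1.61 (SE 0.23, adjusted p = 0.00528) and Ldha by 1.27 (SE 0.22, adjusted p = 0.0110). Camera gave adjusted p = 1.15e-06, and 0.241 with an estimated correlation. The lipid-handling macrophage list moved both ways, with 4 of 16 up and 3 down (6 and 3 over the list alone), the cathepsin Ctsk by 5.32 and the cholesterol exporter Abcg1 by 1.36 against -1.30 for Apoe. In camera adjusted p was 0.000198, and 0.317 with an estimated correlation. Of 19 inflammatory cytokine and chemokine genes 6 fell, among them Ccl2 at -1.54 and Nfkbiz at -1.76, and 2 rose and 7 fell over the list alone (camera adjusted p = 0.0994). The immediate early and dissociation stress list, which also reads handling of the tissue, fell in 4 of 20 genes (10 over the list alone), with Jun at -1.77 and Egr1 at -1.64. Camera gave adjusted p = 2.40e-07, and 0.360 with an estimated correlation. With length trends taken out 3 of the 5 glycolysis, 4 of the 7 lipid-handling and 5 of the 6 inflammatory genes stayed called. The 470 called genes (186 up, 284 down) were 115 and 107 without the female and male control, 127 without the DRA female, and 758 and 768 without the female and male library of both exposures. Type 2 dendritic cells held more calls than these macrophages without the DRA female or either control.

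Alveolar macrophages and dendritic cells changed after allergen as well. In alveolar macrophages Ccl17, a chemokine that draws cells bearing CCR4, went from 0.630 ± 0.502 to 18.5 ± 5.68 CPM (log2 change 4.84, SE 0.48, adjusted p = 1.15e-04). The oxysterol enzyme Ch25h went from 27.6 ± 4.17 to 125 ± 43.2 CPM (log2 change 2.19, SE 0.24, adjusted p = 0.00260). The eosinophil attractant Ccl24, also a leading gene of interstitial macrophage cluster 15, was at least 22.9-fold higher (adjusted p = 0.010). In all 4 of 15 alternative activation genes rose in alveolar macrophages and 9 over the list alone. Camera gave adjusted p = 3.45e-16, and 0.218 with an estimated correlation. Immediate early and stress genes fell in 4 of 20 and rose in 1 (6 and 2 over the list alone), with Egr1 at -1.17 (camera adjusted p = 0.0102, 0.585 with an estimated correlation). The prostacyclin receptor Ptgir rose by 2.44 and the ubiquitin ligase Rnf19b by 2.42, while the flagellin receptor Tlr5 and Gabbr1, a GABA receptor subunit, fell by 2.37 and 1.45. Of the inflammatory list 4 of 19 rose, such as the NF-κB inhibitor Tnfaip3 by 1.19 and Cxcl3 by 1.83, and 5 rose and 1 fell over the list alone. Camera gave adjusted p = 2.03e-08, and 0.236 with an estimated correlation. In type 2 dendritic cells, which prime helper T cells, Ccl24 rose from 0 UMIs to 152 ± 27.7 CPM, at least 81.8-fold (adjusted p = 1.01e-06). The oxysterol hydroxylase Cyp7b1 and Pdcd1lg2 were 182-fold (exact 95% interval 50.1 to 1503, adjusted p = 1.12e-04) and 58.5-fold (exact 95% interval 16.0 to 485, adjusted p = 7.36e-04) higher. The lectin Cd209e rose from 8.11 ± 1.58 to 51.7 ± 21.8 CPM (log2 change 2.65, SE 0.39, adjusted p = 6.16e-04). The thyroid hormone receptor Thrb and the zinc finger gene St18 fell by 4.78 and 3.40. Of 14 alternative activation genes 4 rose and 1 fell in them (5 and 1 over the list alone, camera adjusted p = 0.000355, 0.236 with an estimated correlation). Type 1 dendritic cells moved the other way for 2 of 6, with Ccl22 down from 82.1 ± 13.6 to 1.85 ± 2.62 CPM (adjusted p = 0.0233) and Ccl17 at -1.24, 2 over the list alone as well (camera adjusted p = 0.0921). The call of Ccl22 ended with length trends taken out (-5.71, SE 0.96, adjusted p = 0.0598). The 324 calls in type 2 dendritic cells (97 up, 227 down) were 216 and 106 without the DRA female and male and 162 and 177 without the female and male control. The 99 in alveolar macrophages (61 up, 38 down) were 57 and 22 without the female and male control, 186 and 44 without the DRA female and male, and 168 and 164 without the libraries of both exposures.

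In stromal cells and for the remaining lists few genes were called after allergen. The iron-binding lipocalin Lcn2, of the acute phase and metallothionein list and also a leading gene of neutrophil cluster 24, rose by 3.77 (SE 0.42, adjusted p = 0.00161) in alveolar fibroblasts, and the metallothionein Mt2 changed by -1.84 (SE 0.29, adjusted p = 0.0311) in myofibroblasts (smallest adjusted p = 0.344 with an estimated correlation over 5 classes). Haemoglobin Hba-a1, of the list of free RNA, was at least 21.6-fold higher in alveolar fibroblasts too. Myofibroblasts were led by cluster 17.0 (38.1%) after allergen and 17.2 (35.5%) in control. Interferon response genes rose in them in 2 of 18 (6 over the list alone), the ubiquitin-like Isg15 by 2.13 and Ifit3 by 2.42. In camera adjusted p was 7.16e-18, and 0.218 with an estimated correlation. Ccl7, a monocyte attractant of the type 2 chemokine list, rose by 1.96 (SE 0.28, adjusted p = 0.0434) in adventitial fibroblasts. Ltbp2 was the 1 extracellular matrix gene of 19 that rose in alveolar fibroblasts, by 2.10, with 4 over the list alone (adjusted p = 0.361 with an estimated correlation). Endothelin 1 (Edn1), a vessel constrictor, was the 1 of 10 endothelial activation genes that fell in aerocytes, from 15.2 ± 6.04 to 1.30 ± 1.83 CPM (adjusted p = 0.0206, list adjusted p = 0.241 with an estimated correlation). The NRF2 oxidant response list held Slc7a11, the cystine transporter, up by 2.37 in interstitial and 2.00 in alveolar macrophages. No member of the MHC class II list or, in B cells, of the immunoglobulin constant region list was called (smallest adjusted p = 0.236 and 0.603 with an estimated correlation). With length trends taken out Isg15 and Ifit3 in myofibroblasts and Slc7a11 in alveolar macrophages were no longer called at 2.07, 2.4 and 2.27 (adjusted p = 0.0795, 0.194 and 0.0532). Over all classes 1191 genes were called (571 up, 620 down), and 491 and 442 without the female and male control libraries and 1987 (995 up, 992 down) and 2021 without those of both exposures. Rises also outnumbered falls without the DRA female (437 up, 379 down) and male (1033 up, 493 down). Called by edgeR in classical monocytes, CD8 T cells, general capillary cells, neutrophils and natural killer cells were 0 genes each, against 341, 566, 354, 130 and 486 at an unadjusted p under 0.05 and 2, 0, 0, 2 and 1 by DESeq2.

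Ozone against control asks for the effect of a single ozone exposure in lungs without allergen, 1 day later. Cyp1a1, a cytochrome P450 that the aryl hydrocarbon receptor induces (chromosome 9, 57687928 to 57703824, plus strand, GRCm38), fell in both capillary classes. Its level went from 52.7 ± 8.27 to 1.52 ± 0.841 CPM in general capillary cells (log2 change -5.17, SE 0.31, adjusted p = 2.04e-07) and from 97.2 ± 75.7 to 1.66 ± 0.843 CPM in aerocytes (log2 change -5.78, SE 0.36, adjusted p = 1.55e-09), where the control libraries themselves lay far apart. In general capillary cells the chloride channel regulator Clca3a1 rose by 3.59 (SE 0.44, adjusted p = 0.00223), Prrt4 by 2.65 (SE 0.24, adjusted p = 4.72e-05) and Ptgs1, cyclooxygenase 1, by 2.37 (SE 0.37, adjusted p = 0.0247). The heparan sulfatase Sulf1 fell by 2.11. In aerocytes the sulfotransferase Sult1a1 rose by 4.16 (SE 0.50, adjusted p = 0.00112), the coronin Coro6 by 2.05 and Arrdc2 by 1.95, and the membrane metalloproteinase Mmp15 fell by 2.91 (SE 0.28, adjusted p = 8.86e-06). Acute phase and metallothionein genes rose in both, 4 of 17 (5 up and 1 down over the list alone) in general capillary cells and 4 of 15 (7 over the list alone) in aerocytes. The transcription factor Cebpd stood at 1.34 and 1.38 and the metallothionein Mt1 at 2.01 and 2.27. Camera gave that list adjusted p = 9.03e-05 and 4.65e-09, and 0.416 and 0.327 with an estimated correlation. Interferon response genes fell in general capillary cells, 5 of 24 (12 over the list alone), with Ifi44 at -1.26 (SE 0.24, adjusted p = 0.00831) and the GTPase Gbp2 at -0.84. Camera gave p = 9.14e-09 after adjustment, and 0.327 with an estimated correlation. With length trends taken out 3 of the 4 acute phase genes stayed called in general capillary cells and 1 of the 4 in aerocytes, with Mt1 lost at 1.84 and 2.08 (adjusted p = 0.0915 and 0.0887), and Ptgs1 was lost at 2.33 (adjusted p = 0.0896). The 326 calls in general capillary cells (120 up, 206 down) were 10 and 122 without the O3 female and male, 17 without the male control, and 532, 523, 565 and 570 without the DRA female and male and the female and male of both exposures. The 249 in aerocytes (112 up, 137 down) were 52 without the O3 female, 146 and 10 without the female and male control, and 617 and 673 without the female and male of both exposures.

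Acute phase genes also rose in fibroblasts after ozone. In alveolar fibroblasts 4 of 21 members rose (7 over the list alone), the protease inhibitor Serpina3n from 119.6 ± 21.4 to 647 ± 45.1 CPM (log2 change 2.46, SE 0.26, adjusted p = 2.80e-04) and Lcn2 by 2.54. Camera gave adjusted p = 1.31e-11, and 0.327 with an estimated correlation. In myofibroblasts 2 of 16 rose (3 over the list alone), Serpina3n by 4.42 (SE 0.45, adjusted p = 7.10e-05) and Mt2 by 1.59. Camera gave adjusted p = 2.16e-05, and 0.361 with an estimated correlation. Adventitial fibroblasts gained Lbp, which binds bacterial lipopolysaccharide, by 1.80 (SE 0.22, adjusted p = 0.00643). They also gained the fatty acid binding protein Fabp4 by 4.95 (SE 0.39, adjusted p = 1.06e-04) and lubricin, Prg4, by 4.76 (SE 0.39, adjusted p = 0.00359). Col15a1 and the clock gene Npas2 fell by 1.62 each there. Of 19 extracellular matrix genes, Ltbp2 rose there by 2.70, with 4 over the list alone (adjusted p = 0.620 with an estimated correlation). Myofibroblasts gained the matricellular protein Smoc2 by 2.60 (SE 0.43, adjusted p = 0.0157), the clock factor Bhlhe41 by 2.36 and spermidine synthase, Srm, by 2.22, while Prdm15 and Thsd7b fell by 2.20 and 2.17. The share of UMIs in genes that span at least 100000 bases was 16.6 and 16.3% in the female and male ozone libraries of this class against 21.7 and 25.5% in control. Cluster 17.1 led it after ozone (56.4%) against 17.2 in control (35.5%). The 222 calls in myofibroblasts (104 up, 118 down) were 33 and 4 without the female and male control, 29 without the O3 male and between 621 and 812 without a library of the other groups. With each library's trend with gene length taken out 65 were called, and Bhlhe41 and Prdm15 no longer passed, nor did 2 of the 4 acute phase genes in alveolar fibroblasts, with Lcn2 at 2.33 (adjusted p = 0.148).

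By rank, 3 enzymes of cholesterol synthesis, which no fixed list covers, were named in alveolar macrophages after ozone. Sqle, squalene epoxidase, rose from 10.1 ± 0.852 to 57.9 ± 1.53 CPM (log2 change 2.51, SE 0.22, adjusted p = 6.31e-06), Idi1 by 2.37 (SE 0.33, adjusted p = 0.0326) and Fdps by 2.25 (SE 0.23, adjusted p = 8.81e-04). Tppp3, also a marker of ciliated cells, fell by 2.64 (SE 0.20, adjusted p = 6.31e-06) and the potassium channel Kcnk5 by 2.17. Replication genes of the proliferation list rose, 5 of 27 and 11 up with 1 down over the list alone, all 5 of them Mcm helicase subunits such as Mcm6 at 1.63 (SE 0.22, adjusted p = 5.77e-04) and Mcm7 at 1.49. In camera adjusted p was 2.82e-13, and 0.361 with an estimated correlation. Ccl17 and Ch25h rose without allergen too, by 4.00 (SE 0.50, adjusted p = 3.28e-04) and 1.47, 2 of 15 alternative activation genes (3 up and 1 down over the list alone, camera adjusted p = 0.0117, 0.419 with an estimated correlation). In type 1 dendritic cells Ccl17 rose from 237 ± 32.4 to 1760.0 ± 285 CPM (log2 change 2.89, SE 0.26, adjusted p = 4.47e-08), and in interstitial macrophages Arg1 was 24.9-fold (exact 95% interval 8.26 to 123, adjusted p = 0.00576) higher. Glycolytic enzymes rose in interstitial macrophages, 4 of 14 and 6 over the list alone, with Tpi1 at 1.66 and Gapdh at 1.35. Camera gave p = 9.14e-09 after adjustment, and 0.327 with an estimated correlation. In classical monocytes interferon response genes fell, 3 of 22 and 20 over the list alone, with the GTPase Gbp3 at -2.31 (SE 0.37, adjusted p = 0.0162) and Rtp4 at -1.45 (SE 0.23, adjusted p = 0.0162). Camera gave adjusted p = 2.99e-59, and 0.327 with an estimated correlation. Neutrophils, with 28 and 17 cells of cluster 23 here and 1 in control, gained the chemokines Ccl3 by 3.48 (SE 0.37, adjusted p = 0.00766) and Ccl4 by 2.54, 2 of 18 inflammatory genes and 4 over the list alone. Camera gave adjusted p = 5.56e-09, and 0.416 with an estimated correlation. All 4 glycolytic calls in interstitial macrophages were lost with length trends taken out, among them Tpi1 at 1.35 and Gapdh at 1.05 (adjusted p = 0.0676 and 0.0840), while 4 of the 5 Mcm calls stayed. The 73 calls in alveolar macrophages (45 up, 28 down) were 33 and 40 without the O3 female and male, 29 without the male control and between 133 and 139 without a library of the other groups.

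Group 2 innate lymphoid cells held 19 called genes after ozone, among them the type 2 cytokine Il5 at 2.51 and, of the list of free RNA, Igkc at 5.78 and Igha at least 462-fold higher, and Il5 and Igkc lost their calls with length trends taken out (adjusted p = 0.245 and 0.932). Slc7a11, of the NRF2 list and also leading in neutrophil cluster 23, rose in nonclassical monocytes by 1.19, beside S100a9 by 3.28 (adjusted p = 0.136 with length trends taken out). The NRF2 list had a smallest adjusted p of 0.416 with an estimated correlation. The lipid-handling list had Abcg1 at -0.87 in alveolar macrophages. Of 10 endothelial activation genes in aerocytes 1 fell, which is also a marker used to name the class. MHC class II and immunoglobulin genes had 0 calls by edgeR (smallest adjusted p = 0.416 and 0.660 with an estimated correlation). Over all classes 1094 genes were called (498 up, 596 down). That total was 205 without the male control, and 400 and 616 without the O3 female and male, where rises outnumbered falls (285 up, 115 down and 400 up, 216 down). It was 3799 and 3826 without the DRA female and male, and 3031 and 3065 without the female and male of both exposures. CD4, CD8 and regulatory T cells and natural killer cells had 0 calls by edgeR. They had 1286, 1158, 451 and 1440 genes at an unadjusted p under 0.05 and 19, 10, 0 and 18 by DESeq2. Of the class shares 0 were called by edgeR (4 at an unadjusted p under 0.05, smallest adjusted p = 0.147) and 1 without the male control. The exact two-sided permutation test over both ozone groups gave p = 0.171 at its smallest (adjusted p = 0.977).

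Allergen plus ozone against control shows the combined state that the model was built for. Interstitial macrophages made up 5.94 ± 2.32% of cells against 0.714 ± 0.157% in control (log2 change 3.05, SE 0.48, adjusted p = 0.0129). Regulatory T cells made up 1.77 ± 0.696% against 0.332 ± 0.102% (2.42, SE 0.56, adjusted p = 0.0349) and mature dendritic cells 0.936 ± 0.0686% against 0.193 ± 0.139% (2.33, SE 0.57, adjusted p = 0.0349). Adventitial fibroblasts fell by 1.98 on the log2 scale (SE 0.37, adjusted p = 0.0144). The 2 libraries of this group differed in myeloid cells, with 18.0% neutrophils and 9.90% classical monocytes in the male library against 4.39% and 1.66% in the female. The 4 classes called became 1 without the male library of both exposures.

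In CD4 T cells 14 of 16 type 2 lymphocyte effector genes rose and 0 fell, with 14 over the list alone. The class was led by cluster 10.0 (21.1%) with both exposures and by 5.1 (28.8%) in control. Il10 went from 1.88 ± 0.0996 to 63.6 ± 44.7 CPM, and Tnfrsf4 rose by 2.61 (SE 0.20, adjusted p = 2.39e-05) and Areg, a ligand of the epidermal growth factor receptor, by 1.96 (SE 0.23, adjusted p = 3.76e-04). The cytokines Il13 and Il5, at 0 UMIs in control, were at least 49.1-fold and 16.4-fold higher (adjusted p = 1.92e-04 and 0.00777), and Il4 rose by 4.41 (SE 0.89, adjusted p = 0.0219), again without the cells of cluster 10.2. Of the 14, 13 stayed called with length trends taken out. Adjusted p of the list was 1.56e-27 in camera, 0.0374 in fry and 0.134 with an estimated correlation. Of 27 proliferation genes 18 rose and 25 over the list alone, with the topoisomerase Top2a at 2.04 (SE 0.24, adjusted p = 3.67e-04) and Mki67 at 2.19. In camera adjusted p was 1.06e-22, and 0.192 with an estimated correlation. By rank, the fibrinogen-like protein Fgl2 rose by 5.02 (SE 0.36, adjusted p = 2.39e-05) and the checkpoint receptor PD-1, Pdcd1, by 3.74, and Dapl1 and the transcription factor Sox4 fell by 2.01 and 1.62. In regulatory T cells, led by cluster 10.4 (55.7%) here and 10.6 (55.3%) in control, Il10 was at least 32.6-fold, Tmem163 at least 19.3-fold and granzyme B, Gzmb, at least 9.81-fold higher (adjusted p = 0.00835, 1.07e-04 and 1.50e-04). Il10 lost this call with length trends taken out, at an SE of 2.27 against 1.72 before (adjusted p = 0.0808). There 4 of 10 type 2 genes rose (6 over the list alone, camera adjusted p = 6.48e-07, 0.200 with an estimated correlation). The 1043 calls in CD4 T cells (692 up, 351 down) were 170 and 369 without the female and male control, 453 without the male of both exposures, and 1669 and 1692 without the DRA female and male.

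**Figure D3:**
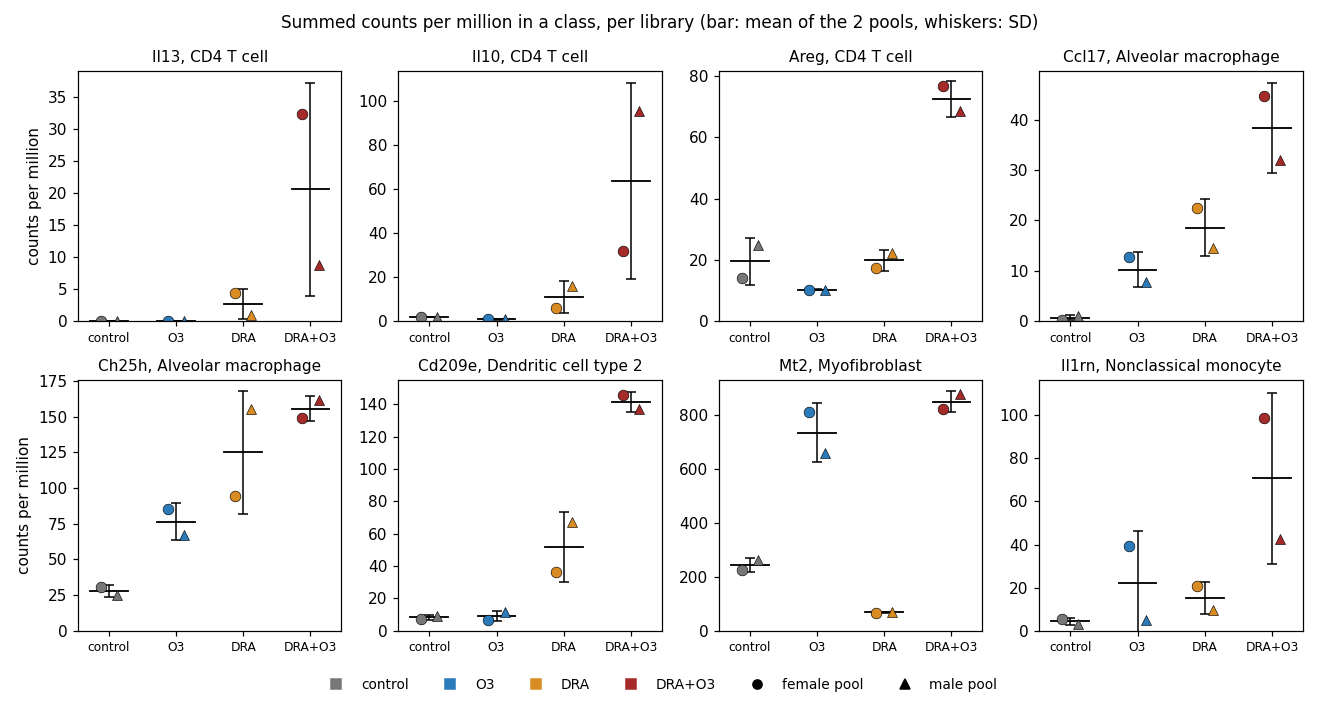
Levels of 8 genes of the fixed lists in CPM, scaled to the UMIs of the class in each library, drawn as the shares above. Il13 in CD4 T cells lay at 0 in control and after ozone and at 20.6 CPM after both exposures.

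Interstitial macrophages held 1366 called genes with both exposures. Chil3 reached 7721 ± 240.5 CPM, 2946-fold (exact 95% interval 1008 to 14290.0, adjusted p = 1.45e-05) above control. Arg1 reached 913 ± 57.5 CPM, 345-fold (exact 95% interval 118 to 1671, adjusted p = 1.15e-06) above control. The activin subunit Inhba and Tarm1 were at least 34.7-fold and 17.4-fold higher. Timd4, a receptor for dying cells on resident macrophages, fell by 6.83 (SE 1.01, adjusted p = 0.00809), and Mmp9, also a neutrophil marker, by 6.52 (SE 1.19, adjusted p = 0.0470). Of 15 alternative activation genes 6 rose (8 over the list alone), Tgm2, a transglutaminase, by 2.15 and the arginine transporter Slc7a2 by 4.32. Adjusted p was 2.69e-15 in camera, 0.0390 in fry and 0.134 with an estimated correlation. Glycolysis genes rose in 10 of 14, also over the list alone, with Pgk1 at 1.73 (SE 0.23, adjusted p = 0.00113), the growth factor Vegfa at 3.15 and Ndrg1 at 2.62. Camera gave adjusted p = 9.34e-07, and 0.200 with an estimated correlation. NRF2 oxidant response genes rose in 6 of 19 (12 over the list alone), Slc7a11 by 3.11 (SE 0.44, adjusted p = 0.00460), the glutathione synthesis enzyme Gclc by 1.43 and haem oxygenase, Hmox1, by 1.34. Camera gave adjusted p = 2.95e-05, and 0.203 with an estimated correlation. Of 16 lipid-handling genes 6 rose and 1 fell (8 and 4 over the list alone), with Ctsk at 6.16 (SE 0.52, adjusted p = 2.93e-04), Gpnmb at 4.64 and Apoe at -1.17. In camera adjusted p was 5.92e-06, and 0.206 with an estimated correlation. Immediate early genes fell in 9 of 20 (2 up and 11 down over the list alone), with Jun at -2.12. Camera gave adjusted p = 2.23e-05, and 0.415 with an estimated correlation. With length trends taken out 5 of the 6 alternative activation, 9 of the 10 glycolysis and 5 of the 6 NRF2 genes stayed called, Hmox1 falling out at 1.18 (adjusted p = 0.0787). The neutrophil transcripts S100a9 and S100a8 rose by 4.43 and 4.13 in the same cells. The 1366 calls (598 up, 768 down) were 614 and 468 without the female and male control and 679 without the male of both exposures.

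Other myeloid classes changed with both exposures as well. In alveolar macrophages 5 of 15 alternative activation genes rose (9 over the list alone), Ccl17 by 5.91 (SE 0.44, adjusted p = 7.46e-07) and Chil3 by 2.07 (camera adjusted p = 6.63e-13, 0.137 with an estimated correlation). Of 27 proliferation genes 9 rose there (12 over the list alone, adjusted p = 0.192 with an estimated correlation). The interferon-induced Ifi211 rose by 3.54, while Dnah11 and the sulfotransferase Chst15 fell by 3.38 and 2.54. In type 2 dendritic cells Ccl24 was at least 278-fold higher (adjusted p = 1.30e-08), the ephrin Efna5 at least 30.1-fold. Cd209e rose by 4.13 (SE 0.36, adjusted p = 8.95e-07), and the potassium channel Kcnq1 and the hydroxylase P3h2 fell by 3.99 and 3.89. There 4 of 14 alternative activation genes rose (5 over the list alone, camera adjusted p = 3.70e-09, 0.134 with an estimated correlation) and 7 of 20 immediate early genes fell (3 up and 10 down over the list alone, adjusted p = 0.327 with an estimated correlation). Antigen presentation genes fell in classical monocytes, where cluster 25 held 47.8% (3 female, 292 male cells). Of 8 MHC class II genes 5 fell (8 over the list alone), the invariant chain Cd74 from 3197 ± 301 to 1326 ± 268 CPM (log2 change -1.26, SE 0.21, adjusted p = 0.0138) and H2-Ab1 at -1.26. This list reached adjusted p = 4.41e-18 in camera, 0.0427 in fry and 0.134 with an estimated correlation. Nonclassical monocytes gained inflammatory genes, 4 of 16 and 10 over the list alone, with the cytokine Il1a at 5.08 (SE 0.73, adjusted p = 0.00181), the interleukin 1 receptor antagonist Il1rn at 4.04 (SE 0.47, adjusted p = 9.15e-04) and the neutrophil attractant Cxcl2 at 2.80. Adjusted p was 2.83e-30 in camera, 0.0427 in fry and 0.134 with an estimated correlation. The call of Chil3 in alveolar macrophages was lost with length trends taken out (2.02, SE 0.46, adjusted p = 0.108). The neutrophil transcripts S100a9 and S100a8 rose by 4.50 and 5.95 in these monocytes (S100a8 at adjusted p = 0.0763 with length trends taken out). Cluster 32.2, with Il1rn and Il1a among its leading genes, held 5.66% of the monocytes and 0% in control. Of the neutrophils cluster 24 held 24.9% (1 female, 302 male cells), and cluster 23, led by Acod1, Il1rn and Cxcl2, had 142 cells in each library and 1 in control. Neutrophils gained Ccl4, Ccl3 and Cxcl3 by 2.49, 2.87 and 3.16, 3 of 18 inflammatory genes and 7 over the list alone. Camera gave adjusted p = 2.73e-06, and 0.372 with an estimated correlation.

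Fibroblasts with both exposures held high acute phase transcripts. In alveolar fibroblasts 5 of 21 members rose (9 over the list alone), Lcn2 from 3.44 ± 3.03 to 129 ± 45.1 CPM (log2 change 5.21, SE 0.36, adjusted p = 3.17e-06) and Serpina3n by 2.04. Adjusted p was 2.74e-25 in camera, 0.0374 in fry and 0.134 with an estimated correlation. Cluster 22, with a median of 1622 UMIs per cell, led this class with both exposures (59.7%), and cluster 20, with 10182.5, in control (60.4%). In myofibroblasts, led by 17.0 (56.1%) and in control by 17.2 (35.5%), 4 of 16 rose (9 over the list alone), Serpina3n by 4.21, complement C3 by 2.84 and Mt2 by 1.80. Camera gave adjusted p = 2.80e-29, and 0.134 with an estimated correlation. Ccl7 rose by 2.52 (SE 0.28, adjusted p = 0.00265) in adventitial fibroblasts, and Ccl8, which attracts type 2 T cells in mice, was 42.2-fold (exact 95% interval 10.9 to 360.5, adjusted p = 0.0187) higher in alveolar fibroblasts. Ccl8 is also a leading gene of interstitial macrophage cluster 15. Of 19 extracellular matrix genes in adventitial fibroblasts 1 rose, Ltbp2 by 3.01, and 15 over the list alone. Camera gave adjusted p = 2.80e-23, and 0.192 with an estimated correlation. Endothelial activation and immunoglobulin genes had 0 calls by edgeR (smallest adjusted p = 0.335 and 0.333 with an estimated correlation). Over all classes 4611 genes were called (2478 up, 2133 down), and 1794 (813 up, 981 down) and 1664 without the female and male control and 2414 without the male of both exposures. Of 154 pairs of a list and a class, 78 passed camera, 16 passed fry and 0 passed with an estimated correlation, against 33 at an unadjusted p under 0.05.

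Allergen plus ozone against allergen asks what ozone added in the sensitised lung, the exacerbation itself. CD4 T cells gained 3 type 2 effector genes of 16 (7 over the list alone). Il13 went from 2.62 ± 2.35 to 20.6 ± 16.6 CPM (log2 change 2.96, SE 0.34, adjusted p = 0.0110). Il10 went from 10.98 ± 7.24 to 63.6 ± 44.7 CPM (log2 change 2.50, SE 0.24, adjusted p = 0.00160) and Areg from 19.8 ± 3.30 to 72.5 ± 5.77 CPM (log2 change 1.90, SE 0.21, adjusted p = 0.00532). The list passed camera (adjusted p = 6.41e-19, and 0.160 with an estimated correlation). Arg1 rose by 1.92 (SE 0.19, adjusted p = 0.00541) in interstitial macrophages. In type 2 dendritic cells Ccl24, also a leading gene of those macrophages, and Cd209e rose by 1.63 and 1.48, 2 of 14 alternative activation genes and 5 over the list alone. Camera gave adjusted p = 8.42e-08, and 0.243 with an estimated correlation. In type 1 dendritic cells Ccl17 rose by 2.31 and Ccl22 went from 1.85 ± 2.62 to 179 ± 110 CPM (adjusted p = 0.00584). CD8 T cells gained 4 of 27 proliferation genes (11 over the list alone), such as Pclaf by 2.42 (SE 0.30, adjusted p = 0.00496) and cyclin A2, Ccna2, by 2.19 (camera adjusted p = 1.12e-23, 0.289 with an estimated correlation). They also gained the ATP receptor P2rx7 by 1.86, while Frat2 and Cirbp fell by 0.97 and 0.94. Clusters 9.1 (26.1%) and 14.0 (23.9%) led CD8 T cells after both exposures and 9.0 (25.5%) after allergen. The 41 calls in CD8 T cells (38 up, 3 down) became 0 by edgeR without the male library of both exposures (542 at an unadjusted p under 0.05) and 4 without the DRA male. They were 8 without either control, 106 and 101 without the O3 female and male, 171 without the DRA female, and 245 without the female of both exposures.

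Genes of endothelium, monocytes, fibroblasts and alveolar macrophages changed with the added ozone. Aerocytes held 169 called genes (130 up, 39 down), among them the hypoxia-induced Ankrd37 at 2.03 (SE 0.30, adjusted p = 8.45e-04), the clock gene Per2 at 1.71 (SE 0.30, adjusted p = 0.00367) and the laminin Lama5 at 1.70. Cyp1a1 fell by 3.12 (SE 0.27, adjusted p = 5.86e-07) and the glutathione transferase Gstt2 by 1.42. In general capillary cells the cell cycle inhibitor Cdkn1a rose from 138 ± 21.3 to 522 ± 224 CPM (log2 change 1.89, SE 0.23, adjusted p = 0.00277). Csrnp1 rose there by 1.80 (SE 0.17, adjusted p = 1.05e-04) and the collagen hydroxylase P4ha2 by 1.61, and the chemokine scavenger Ackr4 and Snhg20 fell by 1.43 and 1.36. Nonclassical monocytes gained the transcription factor Creb5 by 2.69 (SE 0.28, adjusted p = 1.88e-04), the adaptor Cass4 by 2.35 (SE 0.21, adjusted p = 6.80e-05) and the early response gene Ier3 by 2.23. They also gained 4 of 16 inflammatory genes (6 over the list alone), Il1a by 5.02 and Il1rn by 2.13 among them. In camera adjusted p was 5.87e-18, and 0.160 with an estimated correlation. The neutrophil transcript S100a9 rose by 2.59 in these monocytes (adjusted p = 0.126 with length trends taken out) and by 3.95 in interstitial macrophages. Myofibroblasts gained 3 of 16 acute phase genes (11 over the list alone), with Mt2 going from 67.5 ± 2.49 to 849 ± 37.8 CPM (log2 change 3.65, SE 0.29, adjusted p = 7.04e-07) and C3 at 1.84. Camera gave adjusted p = 3.20e-31, and 0.160 with an estimated correlation. In alveolar macrophages fatty acid synthase, Fasn, rose by 1.78 (SE 0.33, adjusted p = 0.0317), the cholesterol synthesis enzyme Nsdhl by 1.70 and Mcm5 by 1.67, and Tppp3, also a ciliated cell marker, fell by 1.09. With length trends taken out Cdkn1a at 2.01 (adjusted p = 0.0714), Gstt2 at -1.26 (0.0776) and Tppp3 at -1.09 (0.156) were no longer called, and 3 of the 4 inflammatory genes stayed called. MHC class II, endothelial activation, glycolysis, extracellular matrix and immunoglobulin genes had 0 calls by edgeR (smallest adjusted p = 0.310, 0.483, 0.483, 0.511 and 0.414 with an estimated correlation). Of the class shares 0 were called (12 at an unadjusted p under 0.05, smallest adjusted p = 0.0936), 7 without either control library and 1 without the female of both exposures. B cells had 0 called genes against 1733 at an unadjusted p under 0.05 and 51 by DESeq2. The aerocyte count was 766 and 66 without the female and male of both exposures, 384 and 6 without the DRA female and male, and 89 and 82 without the female and male control. Over all classes 403 genes were called (318 up, 85 down), and 2868 without the female of both exposures and 616 without the O3 male. Without the DRA female 2852 were called and without the DRA male 234, and falls then outnumbered rises, with 1348 up and 1504 down and with 108 up and 126 down.

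The interaction asks whether ozone acted differently in lungs with and without allergen, and of 610 genes called for it 370 were in aerocytes. The fall of Cyp1a1 was smaller with allergen, by 4.15 (SE 0.40, adjusted p = 2.28e-04) on the log2 scale in general capillary cells and by 2.66 (SE 0.57, adjusted p = 0.0162) in aerocytes. In general capillary cells its mean was 52.7 ± 8.27 CPM in control, 1.52 ± 0.841 after ozone, 53.2 ± 12.9 after allergen and 26.2 ± 6.10 after both. AY036118, a transcript in the ribosomal RNA unit (chromosome 17, 39847113 to 39848035, GRCm38), went the other way, with an interaction of -2.27 (SE 0.28, adjusted p = 3.64e-04) in aerocytes. It stood there at 1684 ± 359 CPM in control, 4459 ± 69.7 after ozone, 2153 ± 139.9 after allergen and 1242 ± 494 after both. Its interaction was -1.86 in general capillary and -2.08 in natural killer cells (adjusted p = 0.0110 and 0.0123). In aerocytes Nup210l had an interaction of 2.44 (SE 0.45, adjusted p = 0.00833), the crystallin Crybb3 of 2.52 and Arrdc2 of -1.89. In general capillary cells the interferon-induced GTPase Gvin1 had one of 2.16 (SE 0.40, adjusted p = 0.0226), Fam71a of 2.55 and Prrt4 of -2.06. Interferon genes had a positive interaction in 1 of 24 in general capillary cells (5 over the list alone), Ifi44 at 1.62. Camera gave adjusted p = 0.000571, and 0.522 with an estimated correlation. Of 10 endothelial activation genes Edn1, Vwf and Apln, the last of which also marks the class, had one in aerocytes (4 genes over the list alone, camera adjusted p = 0.00856, 0.522 with an estimated correlation). The share of UMIs in genes spanning at least 100000 bases in aerocytes was 21.9 and 24.3% in the female and male control, 19.3 and 19.7% after ozone, 23.3 and 21.6% after allergen, and 25.0 and 26.4% after both. With that length trend taken out 180 of 641 genes were called there in place of 370 (257 up, 113 down). Crybb3 at 2.80 (adjusted p = 0.0673), Arrdc2 at -1.58 (0.169), Vwf at 4.52 (0.0783) and Apln (0.0626) were among those lost. The aerocyte count was also 176 of 624 and 24 of 68 without the female and male control, 99 of 315 and 92 of 280 without the O3 female and male, 1016 of 8122 and 40 of 408 without the DRA female and male, and 902 of 3456 without the female of both exposures.

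Interactions were also called in lymphocytes, dendritic cells and myofibroblasts. In CD4 T cells Areg was 1 of 16 type 2 genes with one, at 2.79 (SE 0.36, adjusted p = 0.0230). Its means were 19.4 ± 7.71 CPM in control, 10.2 ± 0.146 after ozone, 19.8 ± 3.30 after allergen and 72.5 ± 5.77 after both, and over the list alone 4 were positive and 1 negative. Camera gave adjusted p = 0.000690, and 0.522 with an estimated correlation. In CD8 T cells 3 of 27 proliferation genes had a positive interaction (12 over the list alone), Pclaf at 3.66 (SE 0.44, adjusted p = 0.00952) and Top2a at 1.94 (camera adjusted p = 7.12e-15, 0.522 with an estimated correlation). Setbp1 stood at 2.75, against the histone gene Hist3h2ba at -2.78 and the kinase Matk at -2.35. Setbp1 lost its call with length trends taken out (2.26, adjusted p = 0.0832). CD8 T cells were led by cluster 9.2 (37.0%) after ozone. In the ozone female library 130 CD8 cells formed a cluster of their own led by the thymocyte genes Arpp21, Cd8b1, Dntt and Rag1. In natural killer cells the interaction of Emb was 1.48 and that of P2ry10 1.23, against -1.76 for Tmem203. In type 2 dendritic cells the receptor partner Ramp3 stood at 2.57 and Gatm, the first enzyme of creatine synthesis, at 2.41 (SE 0.35, adjusted p = 0.00532) against the phosphodiesterase Pde4c at -4.67. Mt2 in myofibroblasts had an interaction of 2.05 (SE 0.37, adjusted p = 0.0490). NRF2, extracellular matrix, glycolysis, MHC class II, lipid-handling and immunoglobulin genes had 0 calls by edgeR (smallest adjusted p = 0.677, 0.725, 0.522, 0.622, 0.522 and 0.622 with an estimated correlation). Alveolar macrophages, interstitial macrophages, neutrophils, classical monocytes and regulatory T cells had 0 calls, with 538, 1001, 276, 780 and 524 genes at an unadjusted p under 0.05 and 0, 10, 0, 15 and 0 called by DESeq2. The 97 genes of CD8 T cells (71 up, 26 down) became 2 and 7 without the female and male control, 6 and 489 without the DRA male and female, and 9 and 349 without the male and female of both exposures. The general capillary count of 110 (87 up, 23 down) was 1 and 2 without the O3 female and male, 167 and 1 without the female and male control, 749 and 26 without the DRA female and male, and 193 without the male of both exposures. Over all classes 610 genes were called (433 up, 177 down). Negative interactions outnumbered positive ones among the 8122 without the DRA female (3961 up, 4161 down), the 408 without the DRA male (185 up, 223 down) and the 3456 without the female of both exposures (1578 up, 1878 down).

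**Figure D4:**
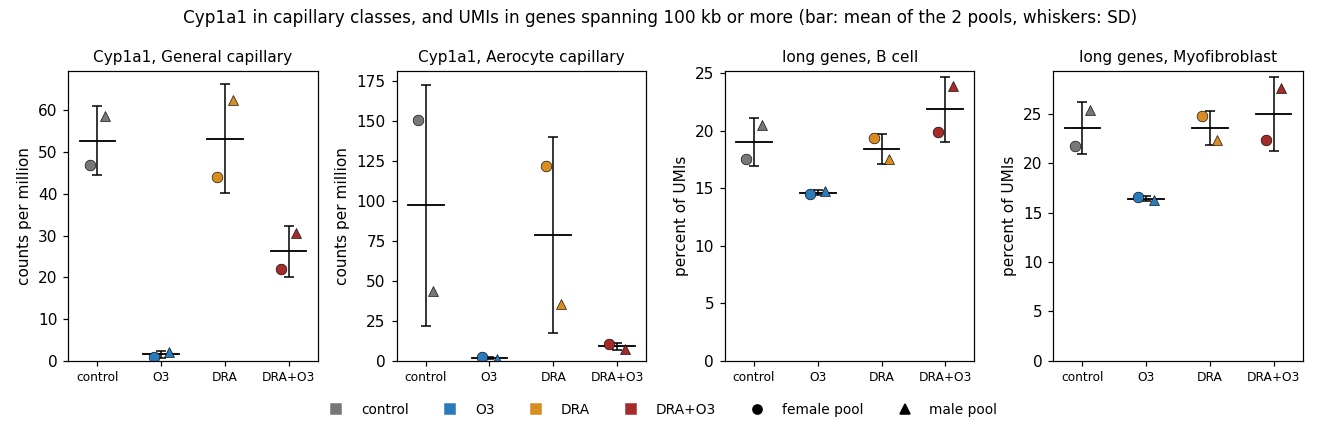
Cyp1a1 in CPM in general capillary cells and aerocytes, and percent of UMIs in genes that span at least 100000 bases in B cells and myofibroblasts, for each library, drawn likewise. Cyp1a1 in general capillary cells lay at 52.7 in control, 1.52 after ozone, 53.2 after allergen and 26.2 CPM after both.

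Male against female, over all exposure groups, checks the labels of the libraries and gives the differences between the sexes. Xist, the transcript that silences an X chromosome in females, was higher in female libraries in 16 of 17 classes tested. Y-linked Ddx3y, Eif2s3y and Uty were higher in males in 17 of 17 classes and Kdm5d in 14 of 14 in which it was measured. These genes matched the labels of all 8 libraries. Tsix, antisense to Xist, was called in 16 of 17 classes, and the X-linked Kdm6a, which escapes X inactivation, in 10. Kdm5c was called in 4 classes and Eif2s3x and Agbl1 in 2 each. Over all classes 201 genes were called (106 up, 95 down), 94 different genes in all. The total was 389 and 400 without the DRA female and male and 351 (174 up, 177 down) and 352 (174 up, 178 down) without the female and male of both exposures.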

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

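Chosen only after the results were seen were the tests of gene length in single classes and over the split of libraries, the counts of splits of the 8 libraries by sex, the test of blood cells, and which classes, genes and clusters are taken up here.

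The effect of ozone differed with and without allergen for 610 genes summed over the classes, by the interaction term of edgeR's quasi-likelihood test, among them 370 in aerocytes, 110 in general capillary cells and 97 in CD8 T cells. For Cyp1a1 the ozone effect with allergen minus that without was 4.15 on the log2 scale in general capillary cells and 2.66 in aerocytes. In aerocytes the mean of Cyp1a1 was 97.2 ± 75.7 CPM in control, 1.66 ± 0.843 after ozone, 78.7 ± 61.0 after allergen and 9.08 ± 2.31 after both (SD, n = 2). With each library's trend with gene length taken out the Cyp1a1 differences were 4.29 (adjusted p = 7.41e-05) and 2.78 (adjusted p = 0.0174).

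Unnamed cluster 10.2 held 198 cells that no class comparison used, and its share lay above that of both control libraries in all 4 libraries with allergen. Its leading genes were Tnfsf8, Cd40lg, the interleukin 33 receptor Il1rl1, Tnfsf11, Il13, the type 2 transcription factor Gata3 and Il4. It made up 0.686% of cells in the DRA female library (exact 95% interval 0.506 to 0.909) and 0.307% in the male (0.201 to 0.450), and 1.05% (0.820 to 1.32) and 0.748% (0.530 to 1.03) with both exposures. In control its shares were 0.0355% (0.00731 to 0.104) and 0.0485% (0.010 to 0.142), and after ozone 0.0855% (0.0314 to 0.186) and 0.0289% (0.00350 to 0.104). These intervals cover counting error only.

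The first pattern is a lean of expression along gene length that follows libraries. With each library's length trend taken out as an offset, 1106 genes were called for allergen and 930 for ozone. Both gave 4801 against control and 479 against allergen, and the interaction 641. Totals before were 1191, 1094, 4611, 403 and 610. Shared were 931, 693, 3953, 313 and 310 calls, which argues against length as the whole cause of those. Totals cannot decide, as new calls enter (B cell interactions went from 1 to 159). In 2 classes the counts fell, from 222 to 65 genes for ozone in myofibroblasts (45 shared) and from 370 to 180 for the interaction in aerocytes (138 shared), where the rank correlation across genes between span and log2 change went from -0.487 and 0.403 to -0.0224 and 0.00420. Bhlhe41 in ozone myofibroblasts lost its call as its log2 change went from 2.36 (SE 0.48, adjusted p = 0.0176) to 2.08 (SE 0.49, adjusted p = 0.0563). So did Prdm15, from -2.20 (SE 0.51) to -2.02 (SE 0.51, adjusted p = 0.0762). Among 448 calls of list genes 65 were lost, all with the same direction and a median ratio of log2 change after to before of 0.966, and the SE was larger after in 46. Cdkn1a in general capillary cells, with both exposures against allergen, lost its call although its change did not shrink. It went from 1.89 (SE 0.23) to 2.01 (SE 0.32, adjusted p = 0.0714). A lean of this kind may come from unspliced or nuclear RNA, and the correction could also remove real change that follows length, so a biological effect of the exposures on long genes stays open and was not tested.

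The second pattern is the split of the 8 libraries by sex, which called 106 genes without exposure terms. In all, 4 of the 35 splits into 4 and 4 libraries called as many or more, but the allergen and ozone splits among them carry the effects of the exposures, so their number does not measure chance. Of the 106 calls, 98 were of Y-linked genes, Xist or Tsix. Only 1 of the 35 splits, that by sex, called as many of these, and the highest other called 1. Sex itself sets these genes, so that outcome checks the labels and cannot measure chance. Autosomal calls numbered 4, and 10 of the 35 splits called as many, among them splits that follow no exposure, so chance cannot be excluded for these. The allergen split called 3566 genes and the ozone split 186. The highest other split called 6134, and such a count, many times that of the sexes, points to a structure of the samples: it sets the female control, both ozone libraries and the DRA male library against the rest and follows no label. Its median rank correlation across genes between gene span and log2 change over 17 classes was 0.339, which is consistent with a share of that structure following gene length.

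The third pattern is the male library with both exposures, which held 18.0% neutrophils and 9.90% classical monocytes against 4.39% and 1.66% in the female. Blood left in the vessels could raise these classes and would bring B cells too. B cells numbered 154 per 100 general capillary cells in the male library and 224 in the female. They numbered 440 and 297 in the female and male control, 318 and 579 after ozone and 1040 and 422 after allergen. With such spread the ratio cannot decide, and blood stays open. Neutrophils numbered 157 against 32.1 and classical monocytes 86.3 against 12.1. A difference between the sexes in the response, or 1 animal of the pool, also stays open and was not tested.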

How the results depend on the processing

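Settings chosen only after the data were seen were the fit with length trends taken out, the fit without clusters of which over 90% came from 1 library, and the robust estimate of dispersion, which moved none of the 6 totals of called genes by over 1.5 times. Among planned settings, DESeq2's size factors, thinned UMIs, all variable genes, a resolution of 1.0 and the stricter filter on cells also left each of these totals within 1.5 times. Without a filter on low counts 3248 genes were called for allergen against control, 5447 for ozone, 9495 for both against control, 3649 for both against allergen, 6090 for the interaction and 1172 for the sexes. With equal cell numbers per class the totals were 505, 658 and 2910 for the comparisons with control, where fewer cells enter. With at least 50 cells per library 782 genes were called for allergen and 1902 for ozone, in 13 classes. With called doublets kept, ozone against control gave 608, both against allergen 234 and the interaction 374, and the cause was not tested. With only the 4 libraries of the compared groups, ozone gave 3245 and both against allergen 147, and DESeq2's Wald test gave 1578 for the interaction. For the list tests, 309 pairs of a list and a class passed camera, 0 passed with an estimated correlation (106 at an unadjusted p under 0.05) and 16 passed fry. Of the median log2 change, the largest shift was 0.0404 with size factors, 0.0444 with thinned UMIs and 0.236 without the filter.

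The replicate numbers share only the sex of the pool. Deviations of same-sex libraries from their group means correlated between -0.0580 and 0.0955 over the 6 pairs of groups, across genes, so the numbers were not taken to pair libraries beyond sex. Without the sex term, which is the replicate block here, 1128 genes were called for allergen, 785 for ozone, 4560 for both against control, 182 for both against allergen and 408 for the interaction, and without exposure terms 106 for the sexes. Shares of 11, 1, 5 and 7 classes were then called for allergen, ozone, both against control and both against allergen.

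Leaving out 1 library leaves its group with a lone library, assumed to vary like the others. The totals then ran from 442 to 2021 for allergen, from 205 to 3826 for ozone, from 1664 to 6660 for both against control, from 234 to 2868 for both against allergen, from 68 to 8122 for the interaction and from 224 to 400 for the sexes. Class shares called ran from 0 to 9 for allergen, 0 to 1 for ozone, 1 to 5 for both against control and 0 to 7 for both against allergen. Other settings moved the share counts to 0 for allergen (6 at an unadjusted p under 0.05) and 3 for both against allergen within immune and other cells separately, to 2 and 6 for ozone and both against allergen with TMM scaling, to 4 for both against allergen with all variable genes, to 7 for both against control with doublets kept, and to 1 and 5 for ozone and both against allergen with the stricter filter, and the cause was not tested.

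Of the values of named genes and list members, 4044 of 5372 (75.3%) kept direction and call when 1 library was left out, 6466 of 7601 (85.1%) under other planned settings and 1940 of 2024 (95.8%) under those chosen later. With equal cell numbers 2 values changed sign, Fabp4 in interstitial macrophages after allergen, at -0.12 in place of 3.55, and S100a9 in nonclassical monocytes after ozone, at -0.54 in place of 3.28. Depth limits genes with few UMIs, such as the cytokines of CD4 T cells, and classes of few cells.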

Other observations

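The totals without clusters from 1 library and the calls with length trends taken out come from settings chosen only after the data were seen, and no hypothesis was tested in this part.

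In aerocytes 2 of 20 immediate early and stress genes had an interaction (5 over the list alone), Egr1 of 1.39 (SE 0.26, adjusted p = 0.00866) and the chaperone Hsp90aa1 of 1.02 (SE 0.24, adjusted p = 0.0253). The list had adjusted p = 0.00308 in camera and 0.677 with an estimated correlation. The neutrophil transcripts S100a8 and S100a9, of the list of free RNA of other cell types, stood at 4.59 and 4.49 in the same cells, and S100a9 lost its call with length trends taken out (adjusted p = 0.0619). Digestion of the tissue can also raise early response and heat shock genes.

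The male library with both exposures supplied 302 of the 321 cells of neutrophil cluster 24 and 292 of the 303 cells of classical monocyte cluster 25, and the ozone female library all 130 cells of CD8 cluster 37. Without these clusters 1191 genes were called for allergen, 1156 for ozone, 4767 for both against control, 498 for both against allergen, 617 for the interaction and 214 for the sexes.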
